A study of Mus musculus with 4 samples.

How the data were processed

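Retinas of C57BL6 mice with the genotype Gbx2-CreERT2-IRES-EGFP and the Ai9 reporter were dissociated and sorted by fluorescence, RNA was isolated with a small-sample kit, and cDNA libraries were prepared with Takara's SMART-Seq kit for ultra low input, per the labels' protocols. Groups were taken from the fluorescence label of each sample: 2 GFP-negative libraries (replicates 2 and 6) and 2 GFP-positive libraries (replicates 2 and 3). The series text describes each animal as the source of a sample of each fraction, so replicates of a fraction are treated as separate animals. Whether replicate 2 names the same animal in both fractions is not given in the sources used here. Other replicates of the stated 4 were not analysed here.

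The authors deposited a table of raw read counts per Ensembl gene, whole numbers with a different total in each library. Trimmomatic, STAR 2.7.3a, MultiQC, limma and the build GRCm38 are named in the submitters' processing notes, with no role or order. The counting tool, its annotation, its strand setting and its treatment of reads that map to several places are not given in the sources used here. Reads of overlapping, antisense or near-identical genes therefore cannot be told apart: Paupar beside Pax6, members of the Trim30 and hemoglobin families, and mitochondrial genes with nuclear copies are uncertain. Spreadsheet software had turned 27 gene symbols into dates, and these were looked up by gene ID. Of 55471 gene IDs, 55144 were found in GENCODE mouse release 21 (GRCm38), which gave coordinates, exonic length and GC content.

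The authors also deposited a second table of signal values, headed as CPM per the file headers, with 18305 rows. Each column was the raw counts times a constant, 100% of values came out as whole reads within 0.01 reads, and 100% of the values shared with the count table were equal to it. Column sums ran from 907000 to 1148000, so the values are relative to a scaled library size; how it was scaled is not given in the sources used here. This table adds a row named GFP. It is named as differential expression results but holds neither fold changes nor p-values in the columns read, so the planned overlap with the authors' comparison was not run.

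Total counts per library were 41040667 to 44689917. A count of 3, taken as the floor for genes at 0, corresponds to 0.0631 to 0.0838 CPM by library; intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Counts were compared with edgeR 4.0.16 in R 4.3.3: TMM scaling (factors 1.017, 0.873, 1.024 and 1.1 for GFP-negative replicates 2 and 6 and GFP-positive replicates 2 and 3), filterByExpr (minimum count 10, minimum total 15), glmQLFit with robust estimation and glmQLFTest, GFP-positive minus GFP-negative. Of 27925 genes with a count, 17940 were tested, with 2 residual degrees of freedom and a median prior of 6.59. Benjamini-Hochberg adjusted p under 0.05 made a call. Standard errors are the absolute log2 fold change over the square root of F. CPM values use effective library sizes, and mean ± SD is over the 2 libraries of a fraction.

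The genes named in the report were fixed by rule before the data were examined, as were the gene lists, the edgeR and camera tests and most alternatives. Genes and tests of the closing section that were chosen after their values were seen are named there. The rule takes Gbx2, the 12 genes per direction with the smallest adjusted p among calls with an absolute log2 fold change of at least 1 and separate groups (leaving out predicted genes, clones and pseudogenes), up to 4 called members of each list, a set of amacrine and guidance genes given whether or not they pass, the most abundant member of each list of another cell type, and Xist and Ddx3y. Values of some genes under this rule are not reported here. A total of 45 gene lists was written from general knowledge of the retina, and 44 had the minimum of 5 tested members. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Some genes stand in more than 1 list, and several markers of other cell types are also expressed by amacrine cells.

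The edgeR, DESeq2 and limma-voom steps were tested on simulated data with the libraries' own means, sizes and spread, 17940 genes, 50 changed at each fold. edgeR recovered 2% of genes changed 2-fold, 42% at 4-fold, 60% at 8-fold and 64% at 16-fold, with 2 false calls (2.33% of calls). In the same data DESeq2 made 71 false calls (39.0% of its calls) and limma-voom 1.

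Alternatives were RLE, upper-quartile and library-size scaling, no filter and a stricter filter (over 5 CPM in at least 2 libraries), DESeq2 1.42.0, limma-voom, a legacy and a non-robust quasi-likelihood fit, a test against a log2 fold change of 1, a replicate block, leaving out each library in turn, and leaving out mitochondrial, hemoglobin, rod and sex-linked genes. Reads recovered from the second table, and offsets for gene length and GC content, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.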

Results

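RNA was sequenced from amacrine cells, the inhibitory interneurons of the inner retina, sorted from dissociated mouse retinas at postnatal days 6 to 7. The mice carried a Gbx2 allele that expresses a tamoxifen-inducible Cre recombinase together with the green fluorescent protein EGFP, and the Ai9 reporter, which makes the red protein tdTomato in cells where Cre has acted and in their descendants. Cells with tdTomato were sorted into a GFP-negative fraction, called cell type 1 in the series, and a GFP-positive fraction, called cell type 2. The files hold 4 libraries, 2 per fraction: GFP-negative replicates 2 and 6, and GFP-positive replicates 2 and 3. The submitters state 4 biological replicates from 3 litters and 750 to 2500 sorted cells per RNA sample. Total gene counts were 41153704 and 41040667 in GFP-negative replicates 2 and 6, and 44689917 and 43272827 in GFP-positive replicates 2 and 3. Between 21363 and 22626 genes had at least 1 count in a library. Pearson correlations of log2 CPM (counts scaled to the effective library size) across genes, which are not independent replicates, were 0.939 between the GFP-negative libraries, 0.915 between the GFP-positive libraries and 0.853 to 0.922 between the fractions. The first principal component held 56.4% of the variance and placed the GFP-negative libraries at -41.8 and -121.8 and the GFP-positive libraries at 33.9 and 129.7. This order of the libraries is also that of their summed rod photoreceptor markers, given below. The component therefore cannot be read as the sort alone. No library was a copy of another: chi-square per degree of freedom between pairs was 148 or more. The lowest value, 148, was between GFP-negative replicate 2 and GFP-positive replicate 2, whose correlation was 0.922. Within the fractions it was 198.7 for the GFP-negative and 166.9 for the GFP-positive libraries, so by this measure the fractions do not group apart.

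The comparison asks how the GFP-positive and GFP-negative cells differ in gene expression, and the genes behind the sort come first as a check of the labels. Gbx2 (ENSMUSG00000034486, a homeobox transcription factor gene on chromosome 1 at 89927956 to 89931179, minus strand, GRCm38) was 13.1-fold higher in GFP-positive cells, at 549 ± 74.8 CPM against 42.1 ± 19.0 CPM (SD, n = 2 per fraction here and throughout). Its log2 fold change was 3.71 ± 0.44 (standard error), with an adjusted p of 0.0118 in edgeR's quasi-likelihood test. A row named GFP, present only in the authors' scaled table, stood at 145 ± 49.4 scaled CPM in GFP-positive and 14.9 ± 7.20 in GFP-negative cells, a 9.78-fold difference (edgeR adjusted p = 0.0152 on reads recovered from that table). Both transcripts were above 0 in the GFP-negative libraries, where the recovered GFP reads numbered 410 and 714 and the Gbx2 counts 1199 and 1988.

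**Figure D1:**
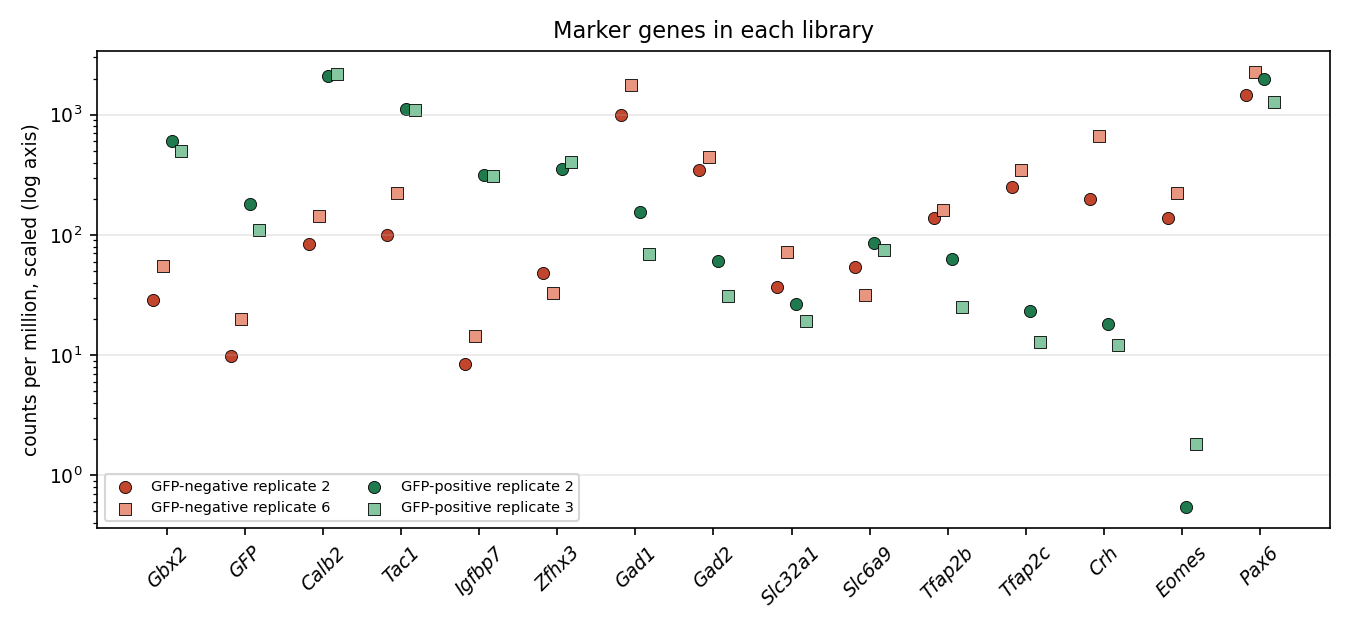
Normalised expression of marker genes in each of the 4 libraries, in CPM on a log axis; each point is 1 library, and the GFP row comes from the authors' scaled table. Gbx2, GFP and Calb2 lie higher in the GFP-positive libraries, and Gad1, Gad2 and Eomes lie lower.

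Of 17940 genes tested, 198 passed an edgeR adjusted p of 0.05: 42 were higher and 156 lower in GFP-positive cells. The median log2 fold change was 3.28 over the higher calls and -3.27 over the lower calls, and the smallest absolute value among calls was 1.72. The common biological coefficient of variation, which measures the spread between replicates, was 55.4%. The CPM ranges of the fractions were separate for all 198 calls and for 43.8% of all tested genes; chance gives 33.3% with 2 against 2. An exact permutation test of a single gene cannot go below p = 0.333 in this design, two-sided, so each call rests on the spread edgeR shares across genes. The count depends on single libraries: it was 1 without GFP-negative replicate 6, 5 without GFP-positive replicate 3, 108 without GFP-positive replicate 2 and 336 without GFP-negative replicate 2. All 198 genes kept their direction in each of those fits. Rod photoreceptor RNA also differed: 16 rod markers summed to 10110 and 2478 CPM in GFP-negative replicates 2 and 6, and to 11459 and 19500 CPM in GFP-positive replicates 2 and 3.

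**Figure D2:**
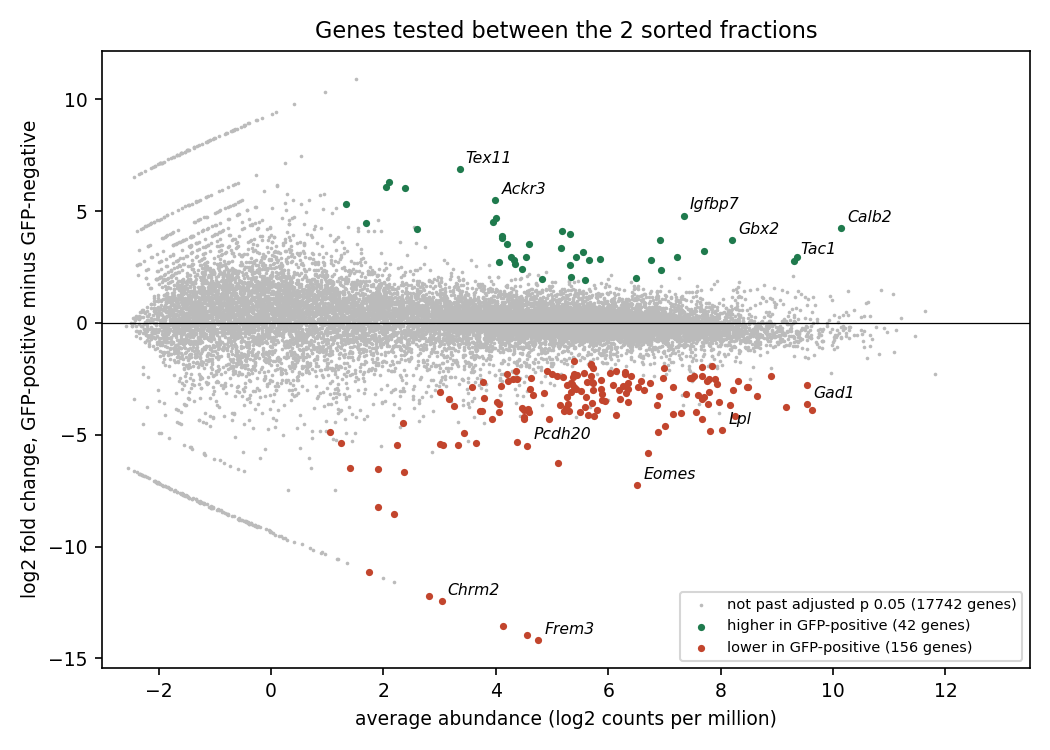
Log2 fold change (GFP-positive minus GFP-negative) against average abundance in log2 CPM for the 17940 tested genes, with the 42 higher calls in green and the 156 lower calls in red. Straight lines of points at the left edge are genes with no or few counts in 1 fraction, whose fitted fold changes depend on the prior count.

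Among the 12 higher genes named by the rule, the largest levels belonged to Calb2 and Gbx2. Calb2 (ENSMUSG00000003657, chromosome 8, 110137502 to 110168210), which encodes the calcium-binding protein calretinin, rose from 114 ± 41.3 to 2146 ± 68.4 CPM (log2 fold change 4.24 ± 0.47, edgeR adjusted p = 0.0107). Igfbp7 (ENSMUSG00000036256, chromosome 5, 77349240 to 77408041), a secreted binding protein of insulin-like growth factors, rose from 11.4 ± 4.23 to 314 ± 3.86 CPM (4.79 ± 0.40, edgeR adjusted p = 0.0107). Zfhx3, a zinc finger homeobox factor, rose from 40.6 ± 10.9 to 379 ± 38.1 CPM, and Kctd12, an auxiliary subunit of GABA-B receptors, from 34.1 ± 9.37 to 265 ± 38.6 CPM. Kcnip4, a potassium channel-interacting protein, rose from 27.1 ± 2.05 to 189 ± 60.5 CPM and Col25a1, a membrane collagen, from 17.3 ± 0.52 to 225 ± 131 CPM. Gpc3, a glypican, stood at 3.87 ± 1.09 and 68.1 ± 21.3 CPM in GFP-negative and GFP-positive cells. Low in GFP-negative cells were also Folr1, a folate receptor, Ackr3, an atypical chemokine receptor, Adamts5, an extracellular protease, and Tex11, a gene known from meiosis. They reached 30.9 ± 2.74, 31.0 ± 7.90, 32.3 ± 11.3 and 20.2 ± 2.38 CPM in GFP-positive cells. The rod marker sums given above were also higher on average in the GFP-positive libraries, as was the sum of 11 endothelial and pericyte markers, a list that holds Igfbp7 (557 ± 45.4 against 129 ± 30.9 CPM). Without GFP-negative replicate 6 none of these 12 genes passed, and without GFP-positive replicate 3 the genes that did were Igfbp7, Gpc3 and Col25a1.

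The 12 lower genes named by the rule were led by Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132), a T-box transcription factor gene, which fell from 182 ± 61.0 to 1.19 ± 0.91 CPM. Its log2 fold change was -7.24 ± 0.57 (edgeR adjusted p = 0.0107), and it also passed in every fit that left out a library. Frem3, which encodes an extracellular matrix protein, had 1430 and 2638 counts in the GFP-negative libraries and 0 in both GFP-positive libraries. It was at least 1629-fold lower, taking 3 counts over the group as the floor, which covers counting error only. Lpl, which encodes lipoprotein lipase, fell from 502 ± 120 to 18.2 ± 8.80 CPM, and C1ql2, a secreted C1q-like synaptic protein, from 355 ± 95.3 to 22.4 ± 7.16 CPM. The transcription factor gene Tfap2c fell from 297 ± 68.1 to 18.1 ± 7.39 CPM, the adhesion gene Alcam from 246 ± 70.1 to 9.98 ± 4.66 CPM, and Filip1l from 218 ± 3.94 to 22.4 ± 5.22 CPM. The remaining genes were Pcdh20 (45.8 ± 9.89 to 1.02 ± 0.01 CPM), Ccdc88b (65.4 ± 0.51 to 5.13 ± 0.63 CPM), Chrna2 (42.9 ± 2.82 to 2.21 ± 0.21 CPM), Pdgfd (70.0 ± 18.9 to 4.54 ± 1.40 CPM) and Tenm1 (84.8 ± 35.9 to 5.35 ± 0.14 CPM). Apart from Eomes, none of the 12 passed without GFP-negative replicate 6 or without GFP-positive replicate 3.

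Among genes of inhibitory transmission, Gad1 and Gad2 were lower in GFP-positive cells. Gad1 (ENSMUSG00000070880, chromosome 2, 70553072 to 70602014) and Gad2 (ENSMUSG00000026787, chromosome 2, 22622205 to 22693874) encode the enzymes that make GABA. Gad1 fell from 1375 ± 552 to 112 ± 60.3 CPM (log2 fold change -3.62 ± 0.54, edgeR adjusted p = 0.0230). Gad2 fell from 396 ± 66.3 to 46.0 ± 20.9 CPM (-3.10 ± 0.42, edgeR adjusted p = 0.0154). Gad1 did not pass without GFP-negative replicate 6 (edgeR adjusted p = 0.126), GFP-positive replicate 2 (0.0907) or GFP-positive replicate 3 (0.295), and Gad2 not without GFP-negative replicate 6 (0.124) or GFP-positive replicate 3 (0.168). The vesicular transporter gene Slc32a1 stood at 54.7 ± 25.3 and 22.9 ± 5.28 CPM (edgeR adjusted p = 0.255). As a list, 2 of 8 GABAergic transmission genes were lower over all genes tested and 5 adjusted over the list alone (median log2 fold change -1.74, camera adjusted p = 1.86e-07; adjusted p = 0.43 with an estimated correlation). Of the glycine genes, Slc6a9, the glycine transporter of glycinergic amacrine cells, stood at 42.9 ± 16.2 and 80.2 ± 7.82 CPM (edgeR adjusted p = 0.334), and Slc6a5 at 4.00 ± 2.24 and 1.38 ± 1.83 CPM (edgeR adjusted p = 0.590). None of the 8 tested glycinergic transmission genes passed over all genes, and 3 were lower adjusted over the list alone (median -1.15, camera adjusted p = 0.016; adjusted p = 0.50 with an estimated correlation). That list did not pass without GFP-negative replicate 6 (camera adjusted p = 0.199) or GFP-positive replicate 3 (0.327).

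Pan-amacrine genes were lower as a list in GFP-positive cells: 2 of 16 over all genes tested (C1ql2 and Tfap2c), and 10 lower with 1 higher adjusted over the list alone (median -1.29, camera adjusted p = 2.66e-09; adjusted p = 0.43 with an estimated correlation). Pax6, the amacrine and eye-field transcription factor gene, stood at 1857 ± 549 CPM in GFP-negative and 1629 ± 485 CPM in GFP-positive cells (edgeR adjusted p = 0.908), and Tfap2b at 149 ± 16.9 and 44.2 ± 27.1 CPM (edgeR adjusted p = 0.135). Markers of amacrine cells that use neither GABA nor glycine (nGnG cells) were higher as a list of 6, with 5 positive log2 fold changes and 1 past over all genes, Gbx2, which was itself used for the sort. Their median was 1.75 (camera adjusted p = 0.000709; adjusted p = 0.43 with an estimated correlation). Other members were low: Neurod6 stood at 0.45 ± 0.24 and 1.86 ± 0.25 CPM, Ebf3 at 2.26 ± 0.28 and 6.51 ± 4.26, and Ppp1r17 at 3.06 ± 1.92 and 2.38 ± 1.05, none past the edgeR threshold. AII amacrine markers had 1 of 8 higher, Calb2 (median 0.51, camera adjusted p = 0.0166; adjusted p = 0.43 with an estimated correlation). That call was lost without GFP-negative replicate 2 (0.113), GFP-negative replicate 6 (0.0673) or GFP-positive replicate 2 (0.181, camera adjusted p in each case), and the AII connexin gene Gjd2 stood at 46.6 ± 27.3 and 34.7 ± 7.29 CPM. Starburst markers did not pass (median -0.56, camera adjusted p = 0.0834), and Chat, the acetylcholine-synthesising enzyme gene of starburst cells, stood at 1.35 ± 0.73 and 1.32 ± 1.87 CPM. Among 20 other named amacrine type markers, Tac1 was higher and Crh and Maf lower (median -0.74, camera adjusted p = 0.0294; adjusted p = 0.43 with an estimated correlation). That call was lost without GFP-negative replicate 2 (camera adjusted p = 0.116) or GFP-positive replicate 3 (0.0631), and the median was 0.45 under a stricter filter on low counts (camera adjusted p = 0.435). Lhx9 stood at 253 ± 80.5 and 334 ± 166 CPM and Slc17a8, the vesicular glutamate transporter of some amacrine cells, at 0.16 ± 0.18 and 0.62 ± 0.88 CPM.

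Neuropeptide genes moved both ways. Tac1, which encodes substance P, rose from 161 ± 86.3 to 1108 ± 10.1 CPM (edgeR adjusted p = 0.0342), and Nxph1, a neurexophilin, from 6.34 ± 3.44 to 65.1 ± 14.3 CPM (edgeR adjusted p = 0.0154). Crh, which encodes corticotropin-releasing hormone, fell from 432 ± 330 to 15.2 ± 4.24 CPM (edgeR adjusted p = 0.0131). Tac1 passed in none of the fits that left out a library (edgeR adjusted p = 0.0517 to 0.214). Of 21 tested members, 2 were higher and 1 lower over all genes, and 2 and 10 adjusted over the list alone. The list was lower (median -1.22, camera adjusted p = 0.00348; adjusted p = 0.43 with an estimated correlation), except under a stricter filter on low counts (camera adjusted p = 0.288).

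Several lists of receptor genes were lower by camera at the preset correlation in GFP-positive cells, whose libraries had the higher mean rod marker sum, 15479 against 6294 CPM. Few of their members passed on their own. Among 36 receptors for amines, acetylcholine and peptides, 5 were lower over all genes and 12 adjusted over the list alone (median -1.21, camera adjusted p = 2.46e-09; adjusted p = 0.43 with an estimated correlation). Chrm2, a muscarinic receptor gene, had 484 and 754 counts in GFP-negative and 0 in both GFP-positive libraries, at least 495.8-fold lower. Chrna4, a nicotinic subunit gene, fell from 134 ± 63.2 to 18.9 ± 8.54 CPM, Chrm1 from 16.4 ± 3.69 to 1.54 ± 0.48, and Drd5, a dopamine receptor gene, from 19.6 ± 13.0 to 0.43 ± 0.58. Metabotropic glutamate receptors had 2 of 8 lower, Grm8 (96.2 ± 43.7 to 8.02 ± 3.91 CPM) and Grm4 (99.3 ± 49.5 to 17.1 ± 5.66 CPM), and 6 lower with 1 higher adjusted over the list alone (median -2.14, camera adjusted p = 3.88e-05; adjusted p = 0.43 with an estimated correlation). In the list of 19 AMPA and kainate receptor genes, 3 auxiliary subunits were lower: Cacng5, Cacng3 (623 ± 309 to 85.4 ± 42.8 CPM) and Cnih3. Adjusted over the list alone there were 6 lower and 1 higher (median -0.59, camera adjusted p = 3.25e-06; adjusted p = 0.43 with an estimated correlation). None of 6 NMDA receptor subunits passed over all genes (3 lower and 1 higher adjusted over the list alone; median -1.31, camera adjusted p = 0.0294; adjusted p = 0.45 with an estimated correlation), and the list did not pass without GFP-negative replicate 6 (camera adjusted p = 0.192) or under a stricter filter (0.0627). None of 17 GABA receptor subunits passed over all genes (6 lower and 1 higher adjusted over the list alone; median -0.93, camera adjusted p = 0.000822; adjusted p = 0.43 with an estimated correlation), and the list did not pass without GFP-positive replicate 3 (camera adjusted p = 0.0875).

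Of 44 potassium and HCN channel genes, Kcnip4 was higher and 4 were lower over all genes, among them Kcnip1 (370 ± 132 to 35.4 ± 12.6 CPM), Kcnab1 (141 ± 2.88 to 21.6 ± 8.70 CPM) and Kcnk9 (30.7 ± 11.7 to 2.50 ± 0.52 CPM). Adjusted over the list alone, 15 were lower and 1 higher (median -0.81, camera adjusted p = 1.41e-09; adjusted p = 0.43 with an estimated correlation). Among 11 voltage-gated sodium channel genes, the leak channel gene Nalcn fell from 128 ± 65.6 to 28.1 ± 2.18 CPM, and it was also the 1 member adjusted over the list alone (median -0.53, camera adjusted p = 0.0459; adjusted p = 0.46 with an estimated correlation). That list did not pass without GFP-negative replicate 6 (camera adjusted p = 0.103), without GFP-positive replicate 3 (0.327) or under a stricter filter (0.0833). Voltage-gated calcium channels (17 tested, median -0.001, camera adjusted p = 0.535) and connexins and pannexins (11 tested, median -0.57, camera adjusted p = 0.0759) did not pass. The connexin list passed without GFP-negative replicate 2 (camera adjusted p = 0.0374) and with library size as the only scaling (0.0497). Synaptic vesicle release genes were lower as a list of 43 with none past over all genes (6 lower and 1 higher adjusted over the list alone; median -0.60, camera adjusted p = 0.00023; adjusted p = 0.45 with an estimated correlation). Calcium-binding protein genes did not pass as a list of 22 (median -0.03, camera adjusted p = 0.646): Calb2 was higher and Pcp4l1 lower (461 ± 176 to 40.3 ± 15.4 CPM).

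Genes of cell contact and synapse assembly were among the lower lists. Of 46 synaptic organizers, 7 were lower over all genes and 15 adjusted over the list alone (median -0.54, camera adjusted p = 6.14e-12; adjusted p = 0.43 with an estimated correlation). They included C1ql2, Tenm1, Cbln4 (58.3 ± 37.8 to 2.99 ± 0.69 CPM) and Lrrtm1 (151 ± 76.3 to 13.0 ± 6.82 CPM). Of 33 cadherins and protocadherins, 7 were lower and 1 was higher over all genes, and 13 and 2 adjusted over the list alone (median -0.76, camera adjusted p = 6.99e-08; adjusted p = 0.43 with an estimated correlation). Among the lower members were Pcdh20, Pcdh19 (405 ± 230 to 32.7 ± 9.73 CPM), Cdh8 (94.3 ± 16.7 to 11.7 ± 4.83 CPM) and Cdh12 (89.3 ± 7.78 to 6.64 ± 5.73 CPM). Immunoglobulin-family adhesion genes had 4 of 45 lower, over all genes and adjusted over the list alone: Kirrel3 (381 ± 214 to 38.1 ± 15.7 CPM), Lsamp, Cntn5 and Mdga1 (median -0.20, camera adjusted p = 0.0304; adjusted p = 0.63 with an estimated correlation). The list did not pass without GFP-negative replicate 6 (camera adjusted p = 0.837), without GFP-positive replicate 3 (0.183) or under a stricter filter (0.130). Of 43 Slit, Robo, netrin and semaphorin guidance genes, Sema6d (71.6 ± 31.7 to 5.88 ± 4.15 CPM) and Unc5d (69.2 ± 15.2 to 14.3 ± 4.2 CPM) were lower over all genes, and 11 lower with 4 higher adjusted over the list alone (median -0.42, camera adjusted p = 0.0392; adjusted p = 0.63 with an estimated correlation). That list did not pass without GFP-negative replicate 6 (camera adjusted p = 0.263), without GFP-positive replicate 3 (0.977) or under a stricter filter (0.0557). Robo1 stood at 335 ± 104 and 181 ± 115 CPM and Robo2 at 211 ± 75.6 and 222 ± 152 CPM. None of 21 ephrins and Eph receptors passed (median -0.32, camera adjusted p = 0.0834), although the list passed without GFP-negative replicate 2 (camera adjusted p = 0.0165) or GFP-positive replicate 2 (0.00589).

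Transcription factor genes had members on each side. Among 47 homeobox and LIM factors, Gbx2 and Zfhx3 were higher, and Lmo4 (374 ± 128 to 61.1 ± 6.53 CPM) and Lmo3 were lower. Lmo3 had 482 and 229 counts in GFP-negative and 0 and 2 in GFP-positive libraries, a ratio of 0.00234 with a 95% counting interval of 0.000283 to 0.00849. Adjusted over the list alone, 4 were higher and 4 lower (median 0.60, camera adjusted p = 0.0294; adjusted p = 0.43 with an estimated correlation). The list did not pass without GFP-negative replicate 6 (camera adjusted p = 0.158) or GFP-positive replicate 2 (0.0965). Among 54 bHLH, NFI, EBF and other neuronal factors, 5 were lower over all genes, and 13 lower with 4 higher adjusted over the list alone. Its median was 0.32 while its mean was -0.22 and the test pointed down (camera adjusted p = 0.066); it passed with no filter on low counts (0.0423) and with library size as the only scaling (0.0497). The lower members included Tfap2c, Nr4a2 (535 ± 245 to 41.5 ± 8.98 CPM), Maf (69.9 ± 27.7 to 6.95 ± 1.08 CPM) and Prdm8 (376 ± 58.0 to 65.9 ± 1.32 CPM).

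**Figure D3:**
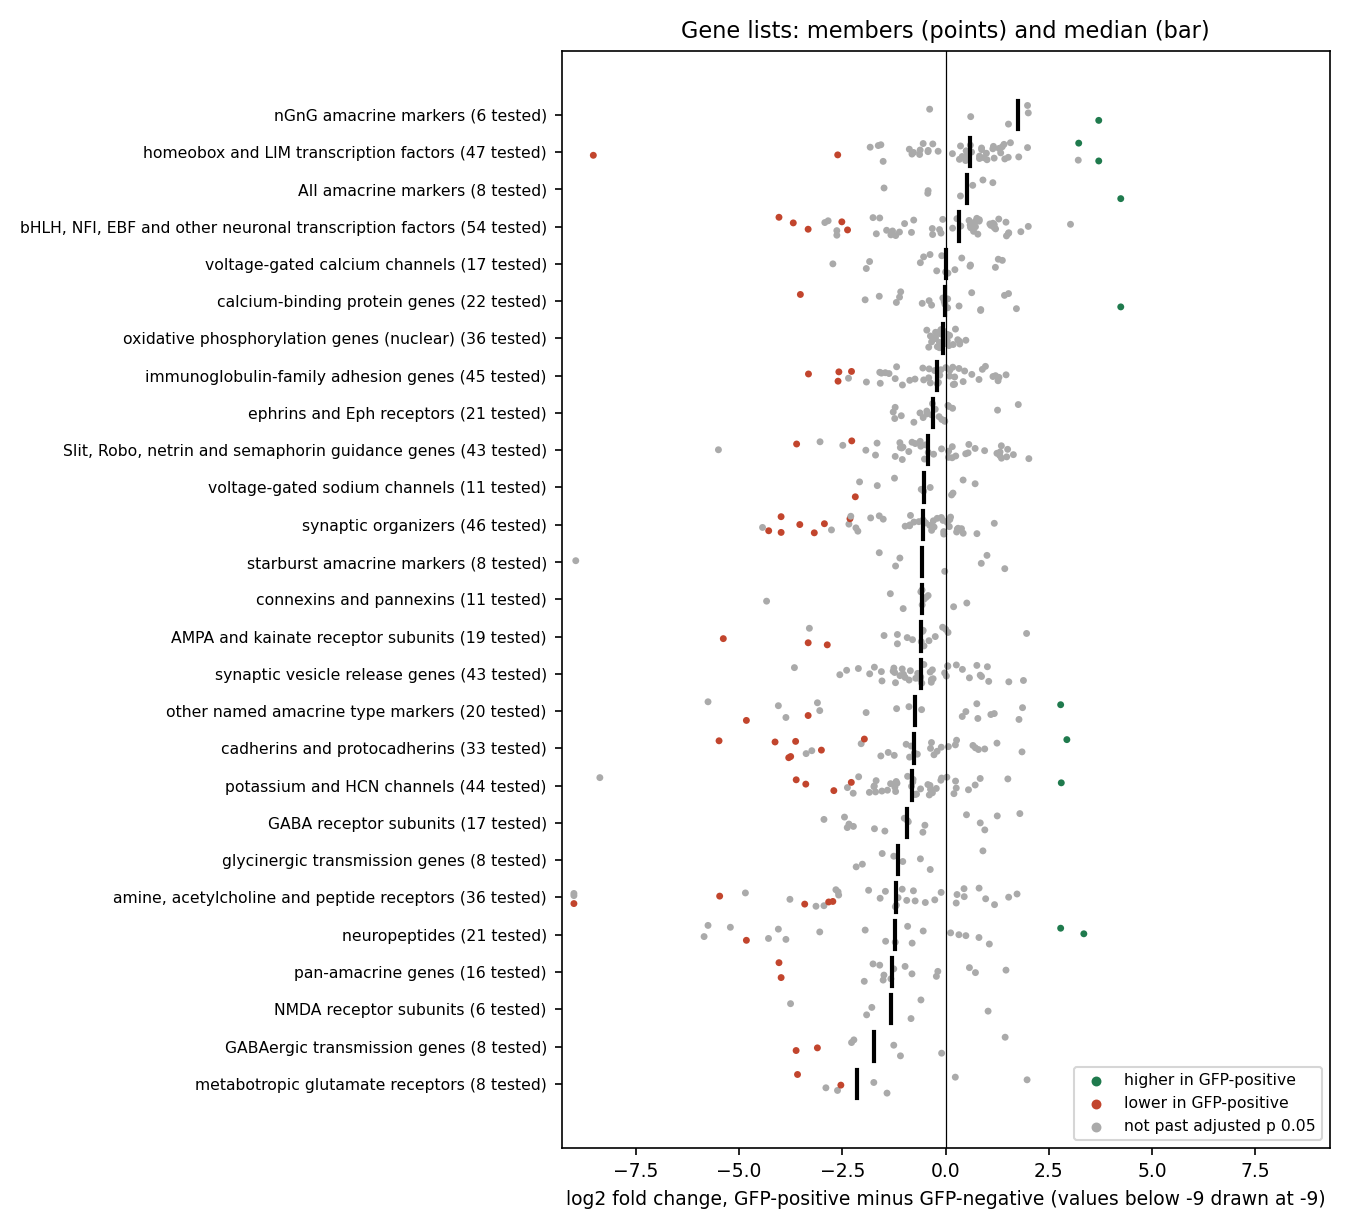
Log2 fold changes (GFP-positive minus GFP-negative) of the tested members of each amacrine and functional gene list, 1 point per gene, with the list median as a black bar and calls in colour. Lists with a median below 0 predominate, and metabotropic glutamate receptors have the lowest, at -2.14.

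Markers of other retinal cell types were measured to show what else the sorted fractions held. Rod markers were higher as a list in GFP-positive cells, all 16 with a positive log2 fold change and none past over all genes or adjusted over the list alone. They summed to 15479 ± 5686 CPM against 6294 ± 5397 CPM (median 1.33, camera adjusted p = 1.48e-07; adjusted p = 0.45 with an estimated correlation). Sag, which encodes rod arrestin, stood at 1254 ± 1049 CPM in GFP-negative and 3052 ± 1301 CPM in GFP-positive cells. Cone markers were higher as a list of 11 with none past (median 1.36, camera adjusted p = 0.00697; adjusted p = 0.60 with an estimated correlation), a call lost without GFP-negative replicate 6 (camera adjusted p = 0.281) or GFP-positive replicate 3 (0.204). The cone opsin gene Opn1sw stood at 114 ± 135 and 252 ± 117 CPM. Bipolar cell markers were higher as a list of 17 with none past (median 1.16, camera adjusted p = 0.000592; adjusted p = 0.43 with an estimated correlation), and Gnao1, which amacrine cells also express, stood at 508 ± 139 and 394 ± 43.0 CPM. Endothelial and pericyte markers were higher as a list of 11, with 10 positive log2 fold changes, 1 past over all genes (Igfbp7) and 4 adjusted over the list alone (median 1.55, camera adjusted p = 8.07e-06; adjusted p = 0.43 with an estimated correlation), and not without GFP-positive replicate 3 (camera adjusted p = 0.101). Red blood cell genes were higher as a list of 5 with none past. Their median was 1.70 (camera adjusted p = 0.016; adjusted p = 0.43 with an estimated correlation), and the call was lost without GFP-negative replicate 6 (camera adjusted p = 0.0829).

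Retinal ganglion cell markers were lower, with Eomes the 1 of 15 past over all genes, and 3 lower with 1 higher adjusted over the list alone (median -0.37, camera adjusted p = 0.00697; adjusted p = 0.45 with an estimated correlation). That call was lost without GFP-positive replicate 3 (camera adjusted p = 0.0606), and the neuronal gene Stmn2 stood at 579 ± 241 and 447 ± 109 CPM. Müller glia markers did not pass (15 tested, median 0.27, mean -0.09, test direction down, camera adjusted p = 0.839), and their member Dkk3 fell from 1293 ± 403 to 187 ± 79.9 CPM (edgeR adjusted p = 0.0342). Horizontal cell markers (8 tested, median 0.92, camera adjusted p = 0.579; Ndrg1 at 222 ± 211 and 467 ± 120 CPM) and cell cycle genes (15 tested, median 0.63, camera adjusted p = 0.117; Pcna at 50.2 ± 1.94 and 42.8 ± 5.74 CPM) did not pass. Astrocyte markers (6 tested, median -0.999, camera adjusted p = 0.187; Aldoc at 100.5 ± 5.68 and 58.6 ± 17.9 CPM) passed as lower without GFP-negative replicate 6 (camera adjusted p = 0.0179). Microglia and macrophage markers (12 tested, median -0.03, camera adjusted p = 0.494) passed as lower without GFP-positive replicate 3 (camera adjusted p = 0.00104). Pigment epithelium markers (6 tested, median 1.70, camera adjusted p = 0.389; Dct at 45.9 ± 30.2 and 130 ± 14 CPM) passed as higher without GFP-positive replicate 2 (camera adjusted p = 0.0226).

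**Figure D4:**
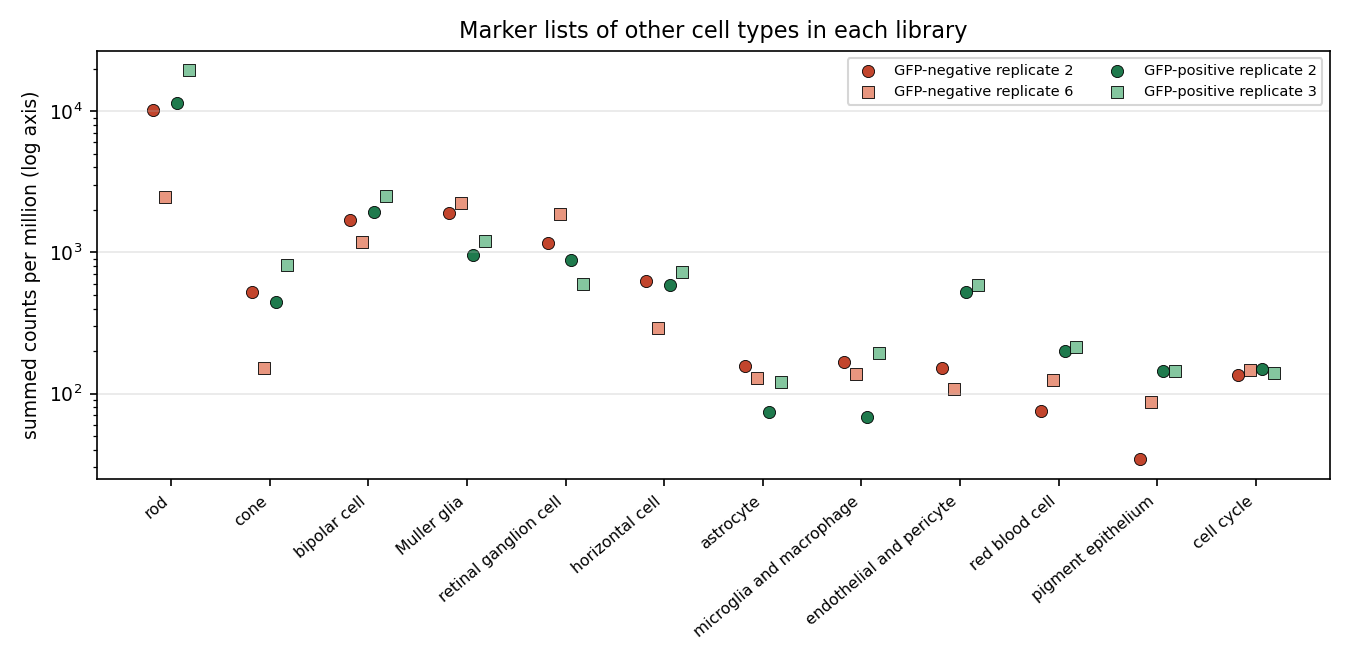
Summed CPM, on a log axis, of the marker lists of other cell types in each of the 4 libraries. Rod markers have the highest sums, from 2478 in GFP-negative replicate 6 to 19500 in GFP-positive replicate 3.

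Lists that track RNA quality did not separate the fractions in the fit of all 4 libraries. Mitochondrially encoded genes held 0.74% and 0.19% of counts in GFP-negative replicates 2 and 6 and 0.51% and 0.66% in GFP-positive replicates 2 and 3 (10 tested, median 0.21, camera adjusted p = 0.25). The list passed as higher without GFP-negative replicate 2 (median 1.21, camera adjusted p = 3.1e-05) and as lower without GFP-negative replicate 6 (median -0.37, camera adjusted p = 0.0235). Immediate early and heat shock genes (17 tested, median 0.24, camera adjusted p = 0.115) passed without GFP-negative replicate 2 (camera adjusted p = 0.00783) and with no filter on low counts (0.0467). Apoptosis and damage genes did not pass (14 tested, median -0.04, camera adjusted p = 0.614). Ribosomal protein genes (50 tested, median 0.11, camera adjusted p = 0.328) passed without GFP-positive replicate 2 (camera adjusted p = 0.0122). Nuclear oxidative phosphorylation genes (36 tested, median -0.07, camera adjusted p = 0.623) passed without GFP-negative replicate 2 (camera adjusted p = 0.0228) or GFP-positive replicate 3 (0.018). Sex-linked genes (8 tested, median 0.58, camera adjusted p = 0.0759) passed without GFP-positive replicate 2 (camera adjusted p = 0.046) and with no filter on low counts (0.0423). Only 2 histone genes, H3f3a and H3f3b, were tested, too few for a list test, and neither passed. The Y-linked gene Ddx3y stood at 90.1 ± 0.48 CPM in GFP-negative and 129 ± 54.9 CPM in GFP-positive cells, and Xist had 0 counts in all 4 libraries. Xist overlaps Tsix on the opposite strand, and how such reads were counted is not given in the sources used here, so this 0 sets no limit on its expression. Of the 44 lists tested, 26 passed with the preset correlation, 8 higher and 18 lower, and 0 passed with an estimated correlation, where camera's smallest unadjusted p was 0.0628.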

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

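The fits on recovered reads and with length and GC offsets were chosen after the result was seen; the rest were planned. All 198 calls kept their direction wherever they were tested, but their number moved. Without a filter on low counts 106 genes passed (24 higher, 82 lower), and more genes tested makes the adjustment harsher. DESeq2 called 787 (208 higher, 579 lower), limma-voom 131 (24 higher, 107 lower), the legacy quasi-likelihood fit 48 (13 higher, 35 lower) and the test against a log2 fold change of 1, which asks for more by construction, 73 (19 higher, 54 lower). For the other tools the cause was not tested. On simulated data with 200 changed genes DESeq2 made 71 false calls, 39.0% of its calls. That share depends on how many genes were changed, so it does not carry over to the 787 calls. Leaving out each library in turn gave 1 to 336 calls, 0 to 106 higher and 1 to 230 lower, with the lone library of a fraction assumed to vary like the other fraction. The lowest counts came without GFP-negative replicate 6 (1) and without GFP-positive replicate 3 (5), at 995 and 1440 genes with unadjusted p under 0.05. Of the 60 named genes called, 59 and 56 missed the threshold there, and 2 and 29 without GFP-negative and GFP-positive replicate 2. The count stayed within 1.5 times under the other scalings, the stricter filter, the non-robust fit, the gene exclusions, recovered reads and offsets, at 190 to 280. Library size alone shifted the median log2 fold change of all genes by 0.166.

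Of the 26 lists past the threshold, 26 passed under each other scaling, 18 under the stricter filter, and 24, 17, 24 and 17 without GFP-negative replicates 2 and 6 and GFP-positive replicates 2 and 3; 13 passed in all 4 of those fits. With an estimated correlation 0 passed. The mitochondrially encoded list, not past the threshold with all libraries (median 0.21), reversed without GFP-negative replicate 6 (median -0.37, camera adjusted p = 0.0235). Leaving out each library in turn gave medians of -0.37 to 1.21, and the cause was not tested. No paired analysis was possible because the fractions share only 1 replicate number: a fixed block leaves no residual degrees of freedom, and the correlation of a random block could not be estimated, so that alternative gave no value. With 2 libraries per fraction, changes near 2-fold were mostly below what the test could detect, as the simulated data showed.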

Other observations

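The genes in this paragraph and the next were picked one by one from the calls after their values were seen, so they stand for no gene group. The tests of scaling, of length and GC offsets, of dilution, of Gad1 and Gad2 carry-over and of the rise against rod markers were chosen only after the result was seen. Mc4r, a melanocortin receptor gene, had 1141 and 2404 counts in GFP-negative libraries and 0 in both GFP-positive libraries, at least 1420-fold lower. Prokr2, a prokineticin receptor gene, had 401 and 657 counts against 0, at least 423.7-fold lower. Mc3r fell from 72.1 to 8.40 CPM and Crhr1, the receptor gene for corticotropin-releasing hormone, from 81.1 to 9.82 CPM, all means of 2 libraries. Pcsk1, a gene for a peptide-processing protease, had 645 and 1934 counts against 0, at least 1033-fold lower.

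The chemokine genes Cxcl14 and Cxcl12 fell from 1488 to 101 and from 227 to 7.76 CPM, Fst, which encodes follistatin, from 68.3 to 0.87 CPM, and Npnt, which encodes nephronectin, from 582 to 32.5 CPM, all means of 2 libraries. Higher in GFP-positive cells were Col13a1 (2.87 to 33.7 CPM), Fbn2, a fibrillin gene (0.61 to 11.4 CPM), Ism1 (2.42 to 32.2 CPM), Hmcn1 (4.44 to 33.8 CPM) and the estrogen receptor gene Esr1 (10.1 to 76.4 CPM). Each gene in these paragraphs is among the 198 edgeR calls, and of those, 1 gene passed without GFP-negative replicate 6 and 5 without GFP-positive replicate 3.

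More genes were lower than higher in GFP-positive cells, 78.8% of calls, but 20% (4 higher, 1 lower) without GFP-positive replicate 3, 1 lower gene alone without GFP-negative replicate 6, and 68.5% and 82.4% without GFP-negative and GFP-positive replicate 2. The tables argue against scaling as the whole cause, since at the lowest 73.2% of calls were lower under 3 other scalings, and against gene length and GC content, with 81% after offsets for them. Dilution of amacrine RNA by RNA of rods and other cells would lower genes shared by amacrine cells as much as the lower calls. The lower 95% limit of the pan-amacrine median was -1.63, above the lower calls' median of -3.27 (-3.54 to -3.01). The lower calls were selected by the threshold, and the smallest absolute log2 fold change among calls was 1.72. Part of that gap is therefore fixed by the selection, and the comparison does not settle dilution. Dilution may remain, since the pan-amacrine median was itself -1.29, and a difference between the cell types stays open as a hypothesis.

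Reads of Gad1 and Gad2 in GFP-positive libraries, and of Gbx2 and GFP in GFP-negative libraries, may come from cells carried over between the sorts, which bring every abundant transcript of the other fraction at a like share. Gad1 stood at 11.2% and 5.03% of its GFP-negative mean in GFP-positive replicates 2 and 3. Of 10017 genes with a GFP-negative mean of at least 10 CPM, Chrm2, Pcsk1, Prokr2, Frem3 and Mc4r had 0 counts in both. For these 5 genes the smaller of the Gad1 and Gad2 shares would bring 33.4 to 277 reads per gene and library. Counted as independent reads, these counts of 0 go against carry-over of GFP-negative cells in the proportions of their fraction. They do not exclude it, because reads are not independent molecules and the 5 genes were picked by their counts of 0. In the first test of carry-over of GFP-negative cells into the GFP-positive sort, 8 genes lay, with their upper Poisson limit, below 0.5 times the smaller share. That was short of the 10 set for exclusion. Carry-over of that fraction, as a whole or of a part that lacks those 5 genes, and low expression in the cells themselves stay open. In the test of carry-over of GFP-positive cells into the GFP-negative sort 2 genes, Ackr3 and Tex11, lay below the Gbx2 and GFP limit, within the 2 or fewer foreseen for carry-over, and 0 genes were at 0 in both libraries. A tighter criterion, 10 CPM in each source library, was set after the first counts were seen, with 5 genes for exclusion and 0 for keeping; it gave 6 and 2, so carry-over in the second direction is not settled.

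Higher calls in GFP-positive cells stand beside more rod marker RNA on average, so rod RNA in the sorted fractions was weighed as their source. GFP-negative and GFP-positive replicate 2 had rod marker sums of 10110 and 11459 CPM, while every call had separate CPM ranges between the fractions. A test set beforehand asked whether they follow rod RNA between GFP-negative replicates 2 and 6, where rod markers had a median log2 ratio of 1.95; the higher calls gave -0.57, with an upper 95% limit of -0.49. That limit lay under 0.98, 0.5 times the rod ratio, as foreseen for a source other than rods. Outside that prediction, the median log2 ratios of GFP-positive replicate 3 to 2 were 0.87 for rod markers and -0.45 for the higher calls. These values do not decide whether rod RNA was the source of the higher calls. They cover called genes only, and a call needs a small spread within each fraction. None of the 16 rod markers was called by edgeR, and a gene that follows rods would be missing too. The outcome was therefore largely fixed by the selection of calls. The lower calls gave like values, -0.69 between the GFP-negative replicates and -0.51 for GFP-positive replicate 3 to 2. Against rod RNA as the only source of the rise, 1 of the 42 higher calls, Igfbp7, passed edgeR's test against 1.64, the highest log2 fold change of a rod marker. The other higher calls did not pass that test, so rod RNA stays open for them as a part or the whole of the rise. RNA of further cell types and a biological difference between the fractions also stay open.

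The 4 libraries split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split gave 198 genes, 1 of 3 splits with as many, and the highest of the others gave 0 by edgeR, with 340 and 598 genes at an unadjusted p under 0.05 and no other tool run on them. The other splits mix the fractions in each group. A difference between the fractions then adds to the spread within groups and lowers the count, so 0 is no baseline for chance.

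The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had reads in all 4 libraries, the lowest being 555 for Kdm5d in GFP-negative replicate 6, while Xist and Tsix, which overlap on opposite strands, had 0 counts in each; how overlapping reads were counted is not given in the sources used here, and the series text states at least 1 female sample.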
